A study of Homo sapiens with 9 samples.

How the data were processed

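RNA from A549 cells was sequenced after rRNA depletion with a stranded library protocol, per the labels' protocols. The labels gave 3 groups of 3 biological replicates (stable hairpins against GFP, PRMT5 and MEP50), and libraries were grouped by these labels alone. The authors' deposited count table held whole-number counts of reads per Ensembl gene for the 9 libraries. Per the submitters' processing notes these counts came from reads handled with Trim Galore, STAR and HTSeq on the hg19 build. Versions, the strand setting of the counting and the hairpin sequences were not given in the sources used here. Per the file headers, the authors' 2 deposited comparison tables held the log2 fold changes of DESeq2 and edgeR for each knockdown against the GFP control. Per the file headers, the same deposited tables held an adjusted p-value of DESeq2 and an FDR of edgeR. Their names carry DEp005, read here as a threshold of 0.05 that was not checked against the values.

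The count table held 51796 genes, of which 26748 had a read in some library. Its 5 summary lines of HTSeq were left out of library sizes and tests. Reads outside annotated genes made up 12.1 ± 0.296% of all counted reads in the GFP control, 14.2 ± 0.453% in the PRMT5 knockdown and 13.2 ± 0.753% in the MEP50 knockdown (SD, n = 3), and ambiguous reads 2.36%, 2.35% and 2.34%. Gene names came from a gene-name table that held 44822 of the identifiers (86.5%). Gene lengths, GC content and 3' UTR sequences came from GENCODE release 29, which held 45025 of the identifiers and is built on GRCh38 while the counts were made on hg19, so no coordinates are given.

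Reads on genes numbered 25075508, 29461432 and 27709185 in the control libraries, 25192565, 30735359 and 31586128 in the PRMT5 knockdown libraries, and 20806181, 21622198 and 28663624 in the MEP50 knockdown libraries. Pairs of replicates differed by 3.39 to 4.71 times the variance that counting alone gives (chi-square per degree of freedom), and the biological coefficient of variation was 0.0395.

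Differential expression was tested with edgeR 4.0.16 in R 4.3.3, in 1 fit of all 9 libraries with the group as the only term. TMM scaling (factors 0.99 to 1.01), filterByExpr (14582 genes kept), a robust quasi-likelihood fit and Benjamini-Hochberg adjustment at 0.05 were used. Levels are TMM-scaled CPM with SD over 3 replicates. Log2 fold changes are given with the SE implied by the quasi-likelihood F test (absolute log2 fold change over the square root of F). For large changes of genes with few reads this SE can be smaller than the spread from counting alone. The comparisons were each knockdown against the control and the knockdowns against each other. Shared changes were set against 20 simulations of unchanged groups measured against the same controls. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and, as an alternative, an estimated one. Counts of list members are those past the threshold over all genes, and those adjusted over the list alone are added where they were other than these.

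The 24 lists were methylosome genes, other arginine methyltransferases, epithelial markers, mesenchymal markers and factors of epithelial-mesenchymal transition, TGF-beta pathway components, TGF-beta targets, proteases of invasion, metastasis suppressors, adhesion and basement membrane genes, proliferation genes, p53 targets, replication-dependent histones, core splicing factors, interferon-induced genes, NF-kB and inflammatory genes, sterol synthesis, ATF4 and unfolded protein response genes, NRF2 targets, glycolysis and hypoxia genes, ribosomal proteins, lung lineage genes, mitochondrially encoded genes, fibroblast and stroma markers, and blood and endothelial markers. The last had 2 of 19 members with enough counts and was not tested as a list, which left 23. TXNIP, ITGB3, CCL5, SRXN1, PECAM1 and 30 histone names were not matched to an identifier and were not analysed here.

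The tests of the comparisons and lists, the lists, the alternatives and the rule for naming genes were set before the data were examined, and the closing section names the tests of explanations that were chosen later. The rule named both target genes, the 8 largest rises and 8 largest falls per knockdown (4 each between the knockdowns) among called genes with a mean of at least 1 CPM and no overlap between the libraries of both groups, up to 3 members of each list, and CDH1, VIM, SNAI1, SNAI2, GAS1, TGFB1 and CDKN1A, among others; some genes that the rule named are not reported here. Members named between the knockdowns outside this rule (PLK2, ASNS, VLDLR, GPX2, AKR1C1, COL1A1, RPL27, RPL3 and, in the closing section, YWHAG) were chosen after their values were seen.

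Alternatives were RLE, upper-quartile and library-total scaling, DESeq2 1.42.0, no low-count filter, a filter at 1 CPM in 3 libraries, the replicate number as a block, fits of 6 libraries, removal of 5285 small RNA and mitochondrial genes, stricter thresholds, an estimated correlation for the lists, and leaving out each library in turn. The edgeR test was tested on counts simulated from the control means and the library sizes (14258 genes). In the simulated PRMT5 knockdown 200 genes with a control mean of at least 1 CPM were changed. The simulation left out the gene-by-gene part of the spread that the quasi-likelihood fit estimates. In it the test recovered 76%, 78%, 98% and 100% of genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold, and 5 calls (2.76%) were false. Words of 7 bases were counted in the 3' UTRs of 12024 genes and set against 100 permutations. Trends on transcript length, GC content and mean expression were removed with splines, and intervals came from 2000 bootstrap resamples. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.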

Results

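Gene expression was measured by RNA sequencing in A549 cells, an established human line of lung adenocarcinoma, after stable expression of short hairpin RNAs. The 9 libraries fell into 3 groups of 3 replicates, namely a control hairpin against GFP, a hairpin against PRMT5 and a hairpin against MEP50. PRMT5 is the main enzyme that places symmetric dimethyl marks on arginines of histones and splicing proteins. MEP50, encoded by WDR77, is its WD-repeat partner in the methylosome complex. Between 20806181 and 31586128 reads per library were counted on genes, and 14582 genes had enough counts to be tested. The comparisons asked what each knockdown changed, how far the changes of both partners were shared, and, after the study's title, how genes of the TGF-beta response and of invasion behaved. The first principal component of log2 expression held 52.4% of the variance and separated the control libraries from both knockdowns. The second component held 20.1% and separated the knockdowns from each other.

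Each hairpin lowered its own target to about the same remaining share. PRMT5 (ENSG00000100462) was at 208.5 ± 3.17 CPM (SD, n = 3) in the control, 68.9 ± 1.33 in the PRMT5 knockdown and 203.7 ± 6.35 in the MEP50 knockdown. These levels are 33.1% and 97.7% of the control. Its level was 70.2, 67.5 and 69.2 CPM in the PRMT5 knockdown libraries 1, 2 and 3, against 205.3 to 211.6 CPM in the control libraries and 199.7 to 211 CPM in the MEP50 knockdown libraries. WDR77 (ENSG00000116455) was at 39.4 ± 0.225 CPM in the control, 44.1 ± 2.52 in the PRMT5 knockdown and 12.5 ± 1.58 in the MEP50 knockdown (31.8% of control). Its libraries held 13.6, 10.7 and 13.3 CPM in the MEP50 knockdown, against 39.2 to 39.7 CPM in the control and 42.1 to 46.9 CPM in the PRMT5 knockdown. The log2 fold change of PRMT5 in its own knockdown was -1.60 ± 0.0348 (SE), and that of WDR77 in its own was -1.65 ± 0.075. Their adjusted p was 1.98e-32 and 1.33e-21 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. PRMT5 did not pass the test in the MEP50 knockdown (log2 fold change -0.03, edgeR adjusted p = 0.399). WDR77 was 1.12-fold higher in the PRMT5 knockdown (edgeR adjusted p = 0.03), a call that was lost with DESeq2 (adjusted p = 0.0506). It was also lost when any of GFP control replicates 1, 2 or 3 or PRMT5 knockdown replicates 1 or 2 was left out, with log2 fold changes of 0.15, 0.16, 0.15, 0.16 and 0.11.

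**Figure D1:**
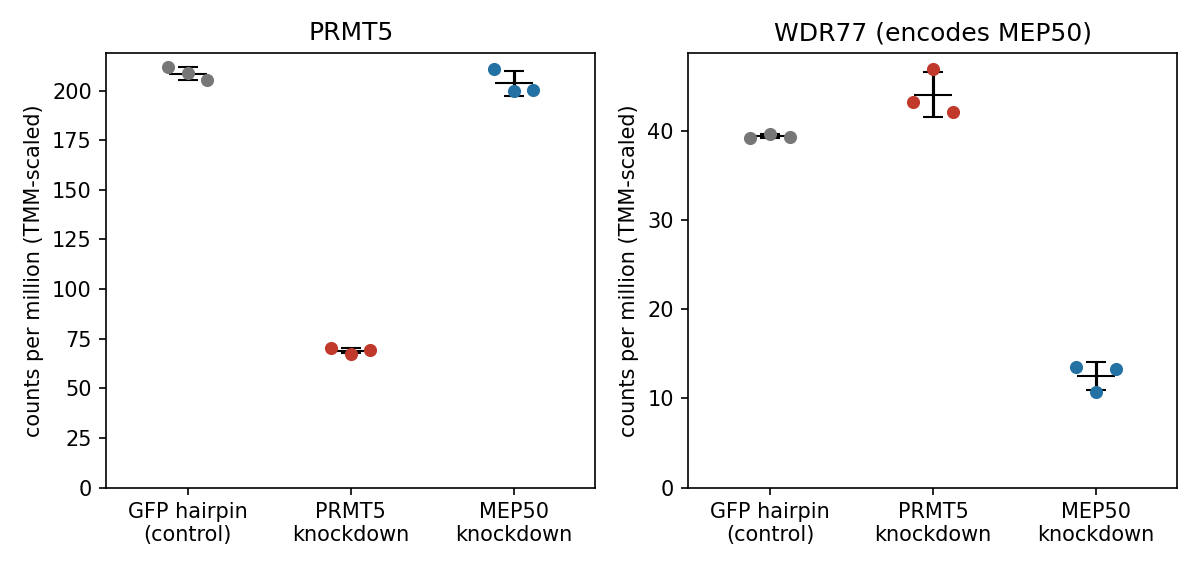
Level of PRMT5 (left) and WDR77, which encodes MEP50 (right), in TMM-scaled CPM, in each library (points) of the 3 groups; black bars give the mean ± SD (n = 3). PRMT5 was at 33.1% of control in its own knockdown and WDR77 at 31.8% in its own, and no library of a knockdown overlapped the control for its target.

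Between the PRMT5 knockdown and the control about as many genes were higher as lower. The labels give 1 hairpin group per target, so the tests cannot part loss of the target from effects of its hairpin or line. Of the 14582 genes, 3809 were higher and 3624 lower than in the control at an adjusted p below 0.05 (edgeR), of which 513 and 544 changed by at least 2-fold and 111 and 153 by at least 4-fold. The collagen chain gene COL5A1 rose from 1.18 ± 0.21 to 77.5 ± 1.16 CPM (log2 fold change 6.05 ± 0.0843, n = 3 per group). DPYSL3, a regulator of the cytoskeleton in neurites, rose from 0.535 ± 0.289 to 20.5 ± 1.42 CPM, the BCL2 family member BCL2A1 from 0.0628 ± 0.0563 to 3.61 ± 0.344 CPM, and the cadherin CDH4 from 0.724 ± 0.103 to 12 ± 0.894 CPM. The potassium channel gene KCNH1 rose 19.3-fold, the sialyltransferase gene ST6GAL2 19.1-fold and DCDC1 20.7-fold. With 5 and 9 reads in the control, the count ratio was 59.5 for BCL2A1 (95% counting interval 25.2 to 184) and 21.7 for DCDC1 (11.2 to 48.2). EVA1A was counted 140 times in the PRMT5 knockdown and 2 times in the control, a ratio of 65.5 with a 95% counting interval of 17.8 to 546. The carboxylesterase gene CES1 fell from 27.8 ± 0.883 to 0.0798 ± 0.0487 CPM, with a log2 fold change of -8.37 ± 0.214. This SE is narrower than the counting interval of CES1 given below. The killer lectin receptor gene KLRC2 fell 81.7-fold, OLAH, which encodes a thioesterase of fatty acid synthesis, 52.4-fold, SCAT8 30.4-fold and the calcium channel subunit gene CACNB2 19.9-fold. Few reads remained for these 5 genes, and the ratio of knockdown to control was 0.00286 for CES1 (7 reads, 95% counting interval 0.00115 to 0.0059), 0.0113 for KLRC2 (5 reads, 0.00367 to 0.0267) and 0.0183 for OLAH (10 reads, 0.00872 to 0.0339). It was 0.0321 for SCAT8 (11 reads, 0.0159 to 0.0583) and 0.0489 for CACNB2 (18 reads, 0.0287 to 0.0785). Genes with abundant transcripts also fell: ceruloplasmin (CP) from 232 ± 6.99 to 6.59 ± 0.993 CPM, the cyclooxygenase gene PTGS2 from 412.5 ± 3.49 to 13 ± 1.16 CPM and neurotensin (NTS) from 264.6 ± 6.26 to 11.2 ± 1.85 CPM. The edgeR adjusted p of these genes was 6.52e-11 (EVA1A) or lower for the rises and 4.53e-14 (SCAT8) or lower for the falls.

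Genes of the TGF-beta response and of the mesenchymal state were mostly higher after PRMT5 knockdown. Of 23 tested TGF-beta target genes, 17 rose and 3 fell (median log2 fold change 0.36), with the growth factor gene PDGFB at 2.32 ± 0.282 and the protease inhibitor gene SERPINE2 at 2.07 ± 0.091, while the proapoptotic BMF fell (-2.27 ± 0.311). The set was higher than other genes by limma's camera with a preset correlation (adjusted p = 0.000121), and adjusted p = 0.246 with an estimated correlation. Of 24 components of the TGF-beta pathway, 15 rose and 5 fell, with the ligand genes TGFB2 at 1.76, TGFB3 at 1.18 and TGFB1 at 1.04 ± 0.0377, and the decoy receptor BAMBI at -1.64 (camera adjusted p = 0.0186, and adjusted p = 0.246 with an estimated correlation). That call was lost without GFP control replicate 1 (adjusted p = 0.0623), where the mean log2 fold change was 0.08. Of 17 mesenchymal markers and transcription factors of epithelial-mesenchymal transition, 9 rose and 3 fell, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.0229, and adjusted p = 0.349 with an estimated correlation). The factors FOXC2 (2.42) and ZEB2 (2.02), the cadherin CDH11 (2.25; 6 reads in the control, count ratio 4.99 with a 95% counting interval of 2.06 to 14.6) and the filament gene VIM (0.54 ± 0.0256, from 744.9 ± 8.28 to 1081 ± 32.6 CPM) rose, and SNAI1 fell (-0.75). SNAI2 had 0.296 ± 0.0332 CPM against 0.186 ± 0.112 in the control and did not pass (edgeR adjusted p = 0.33). The mesenchymal list had a mean log2 fold change of 0.73, and its call was lost with a filter at 1 CPM (0.55, adjusted p = 0.0513) and in a fit of the 6 libraries alone (0.43, adjusted p = 0.119).

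Epithelial genes and genes of adhesion and proteolysis went both ways in the PRMT5 knockdown. Of 15 epithelial markers, 4 rose and 8 fell, or 4 and 9 adjusted over the list alone, and the set was not called (camera adjusted p = 0.3). The epithelial transcription factor ELF3 fell (-1.59), as did the junction genes TJP3 (-1.16) and JUP (-1.08). E-cadherin (CDH1) was at 34.9 ± 2.45 against 40.1 ± 1.64 CPM (log2 fold change -0.20 ± 0.0671, edgeR adjusted p = 0.0131), a call lost without GFP control replicate 1 (-0.18, adjusted p = 0.061) or PRMT5 knockdown replicate 2 (-0.15, adjusted p = 0.0873). Of 20 proteases of invasion and their regulators, 10 rose and 5 fell, or 10 and 6 adjusted over the list alone (camera adjusted p = 0.352), with urokinase (PLAU) at 2.00 ± 0.0507 and ADAM19 at 1.08. Among 18 metastasis suppressors 6 rose and 6 fell (camera adjusted p = 0.728): the scaffold gene AKAP12 fell from 633.2 ± 11 to 159 ± 5.04 CPM and GSN by 1.88-fold, and CCN2 rose 2.08-fold. Of 27 adhesion receptors and basement membrane genes 12 rose and 7 fell (camera adjusted p = 0.134), with the laminin chain LAMB3 at -1.30 and NID2 at -1.31. GAS1 had 0 to 5 reads in each of the 9 libraries and was not tested.

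Cholesterol genes were lower almost throughout after PRMT5 knockdown. Of 25 genes of sterol synthesis and uptake, 23 fell and 2 rose, with a median log2 fold change of -0.72 (camera adjusted p = 1.31e-11, and adjusted p = 0.21 with an estimated correlation). The synthase gene HMGCS1 fell from 1172 ± 10.9 to 433.1 ± 13.7 CPM and the reductase gene TM7SF2 from 15.6 ± 1.43 to 6.25 ± 0.261 CPM. Of 27 targets of the antioxidant factor NRF2, 19 fell and 4 rose, or 20 and 5 adjusted over the list alone (camera adjusted p = 0.000121, and adjusted p = 0.246 with an estimated correlation), led by GPX2 (-2.49), AKR1C1 (-1.31) and AKR1C3 (-1.14). Of 48 ribosomal protein genes, 33 fell and 1 rose, or 34 and 1 adjusted over the list alone, by a median of -0.10 (camera adjusted p = 0.000121, and adjusted p = 0.446 with an estimated correlation), with RPS14 at -0.33, RPL7 at -0.32 and RPL27 at -0.28. Reads of ribosomal protein genes can be shared with their many processed pseudogenes, so single values in this family are uncertain.

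Genes of division, histones and splicing were slightly higher in the PRMT5 knockdown. Of 45 proliferation genes 27 rose and 8 fell (median 0.12), with the mitotic genes CDC20 (0.72), AURKB (0.60) and KIF20A (0.55) leading (camera adjusted p = 0.00424, and adjusted p = 0.254 with an estimated correlation). Of 44 core splicing factors, several of which carry the methylarginines that PRMT5 places, 30 rose and 4 fell, with PRPF3 at 0.64, PRPF4 at 0.41 and PRPF8 at 0.36 (camera adjusted p = 0.000356, and adjusted p = 0.246 with an estimated correlation). Of 23 replication-dependent histone genes 13 rose and 2 fell, with H2BC26 and H2AC25 at 0.41 and H2BC18 at 0.31 (camera adjusted p = 0.046, and adjusted p = 0.644 with an estimated correlation). The histone call was lost without GFP control replicate 2 (mean log2 fold change 0.05, adjusted p = 0.134), PRMT5 knockdown replicate 1 (0.07, adjusted p = 0.0713) or PRMT5 knockdown replicate 3 (0.01, adjusted p = 0.144). Without a low-count filter the mean of the histone list turned to -0.05, while camera still called it higher (adjusted p = 0.0333). Histone genes are near-identical in sequence, and 30 further names of the list were not matched to an identifier and were not analysed here.

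Other lists were not called in the PRMT5 knockdown although single members changed. Of 8 methylosome genes 3 rose and 2 fell (camera adjusted p = 0.955), with RIOK1 at 0.43 and the Sm protein gene SNRPB at -0.22. Of 7 other arginine methyltransferases 3 rose and 1 fell (camera adjusted p = 0.553), with CARM1 at 0.38, PRMT1 at 0.34 and PRMT9 at -0.32, the last lost without GFP control replicate 3 (edgeR adjusted p = 0.0643). Of 34 p53 targets 12 rose and 9 fell (camera adjusted p = 0.511), with PLK2 at 1.15, PLK3 at 0.81, GDF15 at -0.83 and the cell cycle inhibitor CDKN1A at -0.13 (edgeR adjusted p = 0.0117, or 0.0552 without GFP control replicate 2). Of 22 NF-kB and inflammatory genes 12 rose and 6 fell (camera adjusted p = 0.0872), among them PTX3 (3.23), CCL2 (2.64) and PTGS2 (-5.00). This list was called without a low-count filter (adjusted p = 0.0251), in a fit of 6 libraries (0.0459) and without MEP50 knockdown replicate 1 (0.045), with mean log2 fold changes of 0.45, 0.35 and 0.38. Of 37 interferon-induced genes 9 rose and 8 fell (camera adjusted p = 0.785), with OAS1 at -2.19 and PSMB9 at 2.12 and IFIT2 at -1.16. Of 32 genes of the ATF4 and unfolded protein response 11 rose and 9 fell, or 12 and 10 adjusted over the list alone (camera adjusted p = 0.918), with CTH at -2.61, XBP1 at -0.92 and VLDLR at 1.00. Of 35 glycolysis and hypoxia genes 11 rose and 13 fell, or 11 and 14 adjusted over the list alone (camera adjusted p = 0.539), with HK2 at 1.72 and SLC2A3 at -1.53 and ALDOC at -1.32. Of 15 lung lineage genes 6 rose and 2 fell (camera adjusted p = 0.438), with FOXA1 at -1.47, LPCAT1 at 1.20 and ABCA3 at 1.12. Of 13 mitochondrially encoded genes only MT-ND3 passed (-0.15; camera adjusted p = 0.507). Of 7 fibroblast and stroma markers 4 rose and 1 fell (camera adjusted p = 0.0872), with COL3A1 at 1.15 and LUM at -3.06. Of 19 blood and endothelial markers only CD68 (0.56) and ITGAM (0.77) had enough counts to be tested, and 7 had no read in any library. The ITGAM call (edgeR adjusted p = 0.0237) was lost without GFP control replicate 2 (0.74, adjusted p = 0.0697) or 3 (0.52, adjusted p = 0.168) or PRMT5 knockdown replicate 2 (0.67, adjusted p = 0.0938).

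A similar number of genes differed between the MEP50 knockdown and the control, with the same limit of 1 hairpin group. Against the control, 3865 genes were higher and 3675 lower (edgeR adjusted p below 0.05), of which 545 and 550 changed by at least 2-fold and 136 in each direction by at least 4-fold. COL5A1 rose from 1.18 ± 0.21 to 109.3 ± 0.722 CPM (log2 fold change 6.54 ± 0.0819), DPYSL3 from 0.535 ± 0.289 to 43.1 ± 2.67 CPM, ST6GAL2 from 0.427 ± 0.121 to 24.5 ± 1.66 CPM and the receptor tyrosine kinase gene EPHB2 from 2.95 ± 0.484 to 42.5 ± 1.99 CPM. NAV2 rose 27.1-fold, CDH11 36.2-fold and DCDC1 20.4-fold. With 6 and 9 reads in the control, the count ratio was 38.6 for CDH11 (95% counting interval 17.4 to 106) and 21.4 for DCDC1 (11 to 47.7). EVA1A was counted 144 times in the MEP50 knockdown and 2 times in the control, a ratio of 84.1 with a 95% counting interval of 22.9 to 701. CES1 fell from 27.8 ± 0.883 to 0.268 ± 0.118 CPM, the imprinted noncoding RNA H19 from 30.9 ± 1.91 to 0.613 ± 0.197 CPM, NTS from 264.6 ± 6.26 to 10.8 ± 0.604 CPM and CP from 232 ± 6.99 to 12.7 ± 0.816 CPM. OLAH fell 81.7-fold (5 reads left, ratio 0.0114 with a 95% counting interval of 0.0037 to 0.0269), KLRC2 21.5-fold, the activin subunit gene INHBA, a member of the TGF-beta family, 18.4-fold and the potassium channel gene KCNJ2 15.9-fold. CES1 and KLRC2 had 18 and 16 reads left, with ratios of 0.00918 (95% counting interval 0.00543 to 0.0145) and 0.0454 (0.0257 to 0.0746). The edgeR adjusted p of these genes was 7.18e-11 or lower, the highest being that of DCDC1.

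Mesenchymal, stromal and TGF-beta genes were mostly higher after MEP50 knockdown. Of 17 mesenchymal genes 12 rose and 3 fell, or 13 and 3 adjusted over the list alone, by a median of 0.79 (camera adjusted p = 0.000693, and adjusted p = 0.158 with an estimated correlation), with CDH11 at 5.18, FOXC2 at 2.66, ZEB2 at 1.78, VIM at 0.79 ± 0.0257 and SNAI2 at 2.00 ± 0.498 (53 reads against 15), while SNAI1 fell (-0.65). All 7 fibroblast and stroma markers rose (camera adjusted p = 0.000431, and adjusted p = 0.0564 with an estimated correlation), among them COL5A1, COL1A1 (1.44) and COL3A1 (1.41). Of 23 TGF-beta targets 16 rose and 3 fell, with SERPINE2 at 2.41 and PMEPA1 at 1.56 (camera adjusted p = 0.000388, and adjusted p = 0.146 with an estimated correlation). Of 24 pathway components 16 rose and 5 fell, with TGFB1 at 1.13 ± 0.0379, TGFBR3 at -1.64 and BAMBI at -1.44 (camera adjusted p = 0.00885, and adjusted p = 0.158 with an estimated correlation). Of 27 adhesion and basement membrane genes 15 rose and 6 fell, with COL4A4 at 1.88 and L1CAM at -1.47 (camera adjusted p = 0.00885, and adjusted p = 0.102 with an estimated correlation). Of 15 epithelial markers 6 rose and 5 fell (camera adjusted p = 0.837): CDH1 rose from 40.1 ± 1.64 to 75.6 ± 8.5 CPM (0.92 ± 0.0641, edgeR adjusted p = 8.73e-14), and JUP (-1.03) and ELF3 (-1.02) fell. Of 20 proteases of invasion 9 rose and 8 fell (camera adjusted p = 0.944), with ADAM19 at 2.29 and PLAU at 0.97. Of 18 metastasis suppressors 7 rose and 6 fell (camera adjusted p = 0.617), with AKAP12 at -2.63 and CADM1 at 0.62.

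Sterol genes were again lower in the MEP50 knockdown, and p53 targets were higher. Of 25 sterol genes 23 fell and 1 rose, by a median of -0.90 (camera adjusted p = 8.98e-13, and adjusted p = 0.0564 with an estimated correlation), with HMGCS1 at -1.65 and the decarboxylase gene MVD at -1.40. Of 27 NRF2 targets 15 fell and 6 rose (camera adjusted p = 0.0292, and adjusted p = 0.369 with an estimated correlation), with GPX2 at -1.43, AKR1C3 at -0.90 and AKR1B10 at 0.73. Of 34 p53 targets 25 rose and 2 fell, or 27 and 3 adjusted over the list alone, by a median of 0.36 (camera adjusted p = 6.58e-06, and adjusted p = 0.0564 with an estimated correlation). CDKN1A rose from 102.9 ± 2.67 to 163.5 ± 12.5 CPM, the antiproliferative gene BTG2 2.02-fold and TP53I3 1.86-fold, while GDF15 fell 1.94-fold. Of 48 ribosomal protein genes 34 rose, or 37 adjusted over the list alone, and the others did not pass (edgeR), by a median of 0.14 (camera adjusted p = 2.9e-05, and adjusted p = 0.358 with an estimated correlation), with RPS20 at 0.41, RPLP0 at 0.32 and RPL3 at 0.31. Of 13 mitochondrially encoded genes 8 fell, or 9 adjusted over the list alone, with MT-ND5 2.01-fold lower, MT-CYB at -0.97 and MT-ND4L at -0.77, the last lost without MEP50 knockdown replicate 1 (-0.72, edgeR adjusted p = 0.0509) (camera adjusted p = 0.000588, and adjusted p = 0.46 with an estimated correlation). The mitochondrial share of counts was 1.05 ± 0.032% in this knockdown and 1.52 ± 0.263% in the control (SD, n = 3).

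Proliferation genes rose in 31 of 45 cases and fell in 8 in the MEP50 knockdown (camera adjusted p = 0.000438, and adjusted p = 0.146 with an estimated correlation). CDC20 rose (0.68), and the G1/S genes CCNE1 (-1.01) and CDC25A (-0.77) fell. Of 23 histone genes 16 rose and 1 fell, with H2AC21 at 0.39, H1-4 at 0.37 and H2BC26 at 0.34 (camera adjusted p = 0.00108, and adjusted p = 0.432 with an estimated correlation). The mean of this list turned to -0.03 without a low-count filter, while camera still called it higher (adjusted p = 0.000225). Of 44 splicing factors 25 rose and 3 fell, or 26 and 3 adjusted over the list alone, with SNRPE at 0.27, PRPF19 at 0.25 and SNRPA at 0.24 (camera adjusted p = 0.00885, and adjusted p = 0.299 with an estimated correlation). Of 32 ATF4 and unfolded protein response genes 18 rose and 10 fell, or 19 and 10 adjusted over the list alone, with VLDLR at 1.56, ASNS at 1.09 and CTH at -2.10 (camera adjusted p = 0.0331, and adjusted p = 0.291 with an estimated correlation). That call was lost without MEP50 knockdown replicate 2 (mean log2 fold change 0.13, adjusted p = 0.0525). Of 22 NF-kB and inflammatory genes 6 rose and 9 fell (camera adjusted p = 0.359), with CXCL2 at 2.82, PTGS2 at -3.00 and CXCL8 at -2.12. Of 37 interferon-induced genes 10 rose and 6 fell, or 9 and 6 adjusted over the list alone (camera adjusted p = 0.785), with OAS1 at -0.90, DDX60 at 0.61 and PSMB9 at 1.19, the last lost without GFP control replicate 3 (0.84, edgeR adjusted p = 0.0907). Of 35 glycolysis and hypoxia genes 12 rose and 15 fell (camera adjusted p = 0.737), with CA12 at 1.59, ALDOC at -1.34 and SLC2A3 at -1.25. Of 15 lung lineage genes 5 rose and 4 fell (camera adjusted p = 0.366), with HNF4A at 1.57, ABCA3 at 0.94 and LPCAT1 at 0.94. Of 8 methylosome genes 2 rose and 3 fell (camera adjusted p = 0.366), with COPRS at -0.56 and CLNS1A at -0.32 beside WDR77. Of 7 other arginine methyltransferases 3 rose, or 2 adjusted over the list alone (camera adjusted p = 0.359), with CARM1 at 0.64 and PRMT1 at 0.16, and PRMT2 at 0.16 (edgeR adjusted p = 0.0489), which was lost without MEP50 knockdown replicate 3 (0.06, adjusted p = 0.558) and under most other settings. CD68 was at 0.78 and ITGAM at 0.69 (edgeR adjusted p = 0.049). The ITGAM call was lost under 3 other scalings, with DESeq2, without a low-count filter and in a fit of 6 libraries (adjusted p from 0.0509 to 0.0804). It was also lost without GFP control replicate 2 or 3, any PRMT5 knockdown replicate, or MEP50 knockdown replicate 2 or 3 (adjusted p from 0.0507 to 0.253, log2 fold change from 0.45 to 0.69).

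**Figure D2:**
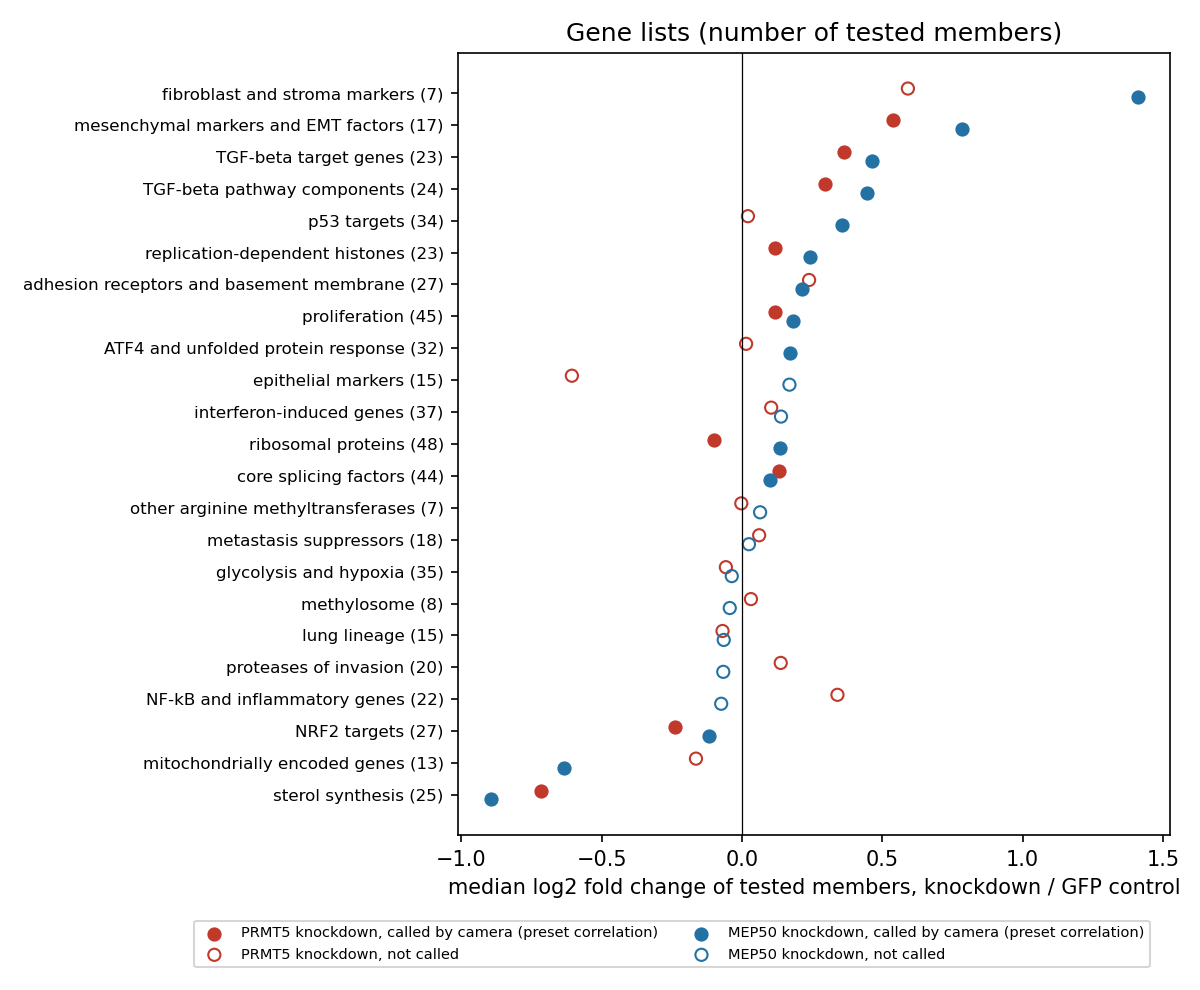
Median log2 fold change against the GFP control of the tested members of each gene list (vertical axis, number of tested members in brackets) in the PRMT5 knockdown (red) and the MEP50 knockdown (blue); filled circles are lists called by camera with a preset correlation and open circles those not called. Sterol synthesis lies lowest in both (-0.72 and -0.90), and ribosomal protein genes lie on opposite sides of 0 (-0.10 and 0.14).

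Many changes were shared by both knockdowns. Higher in both were 2581 genes and lower in both 2267, while 383 passed in both with opposite signs, so that 92.7% of the 5231 genes called in both had the same direction (edgeR). Of the 9742 genes called in either knockdown, 2202 were called in the PRMT5 and 2309 in the MEP50 knockdown only. COL5A1, DPYSL3, ST6GAL2 and EPHB2 were among the shared rises and CES1, CP, NTS and PTGS2 among the shared falls, and at 2-fold or more 319 genes rose and 295 fell in both. Independent lists of the same sizes would share 1010 higher and 913.3 lower genes and hold 1920.5 opposite ones. In 20 simulations of unchanged groups against the same controls at most 3 genes were called in a knockdown and at most 1 was shared in either direction. With so few calls these simulations give no chance value for the overlap of long lists. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.777, against 0.49 on average (0.46 to 0.512) in the simulations. Their covariance was 0.317 against 0.0226 simulated, a difference of 0.294. Both knockdowns were set against the same 3 control libraries, which were not split between them, so part of the excess over independent lists may come from the shared controls.

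**Figure D3:**
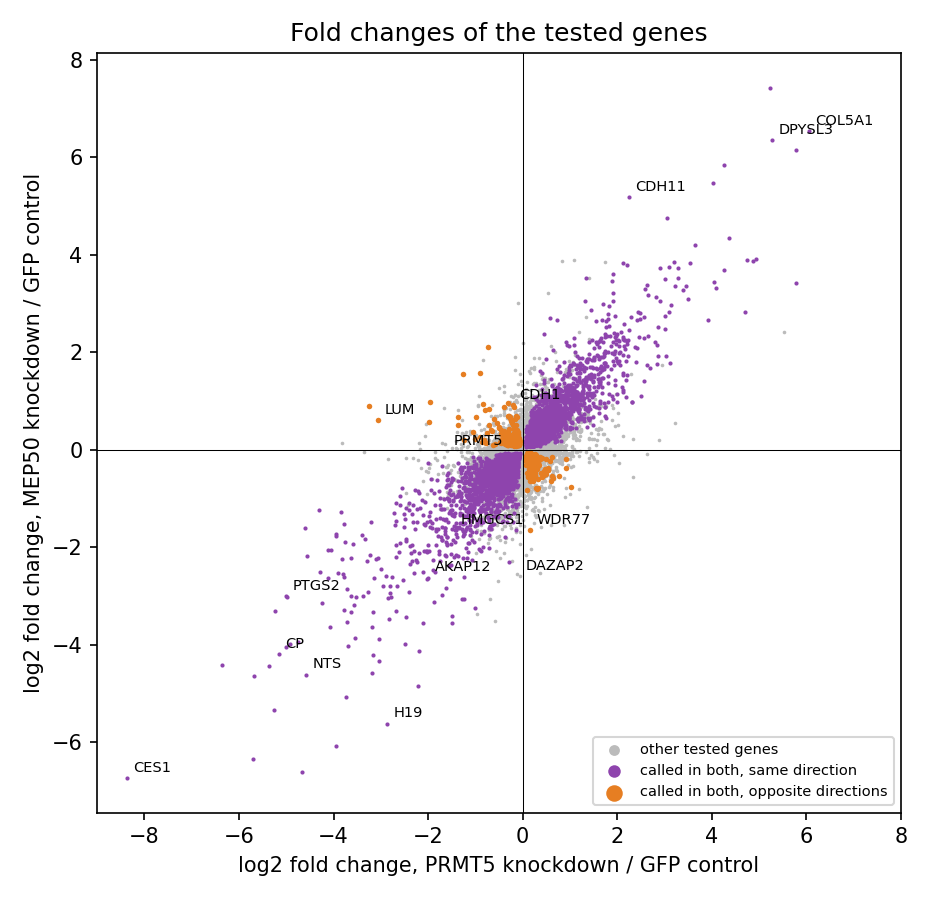
Log2 fold change against the GFP control of 14582 tested genes (points) in the PRMT5 knockdown (horizontal axis) and the MEP50 knockdown (vertical axis). Purple points passed in both in the same direction (2581 higher, 2267 lower), orange points in opposite directions (383), and grey points are the other genes; the Pearson correlation is 0.777.

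Set against each other, the knockdowns differed in fewer genes and by smaller amounts. Between them 2796 genes were higher and 2991 lower in the PRMT5 knockdown (edgeR adjusted p below 0.05), of which 224 and 241 differed by at least 2-fold and 27 and 41 by at least 4-fold. DAZAP2, a small proline-rich protein gene, was at 193.2 ± 8.29 CPM in the PRMT5 knockdown and 33.1 ± 2.99 in the MEP50 knockdown (log2 difference 2.54 ± 0.0467, edgeR adjusted p = 3.2e-32). H19 differed by 2.76, the chemokine gene CCL2 by 2.72 and the pentraxin PTX3 by 2.68, all higher in the PRMT5 knockdown. H19 was nonetheless below its control level of 30.9 ± 1.91 CPM in both, at 4.26 ± 0.254 CPM in the PRMT5 and 0.613 ± 0.197 CPM in the MEP50 knockdown. Lower there were the mucin gene MUC13 (-3.95 ± 0.263), the stromal proteoglycan gene LUM (-3.67 ± 0.209), CACNB2 (-3.08) and CDH11 (-2.93). CDH1 differed by -1.12 (edgeR adjusted p = 2.42e-15), and among the 383 genes of opposite sign 1 changed by at least 2-fold in both directions.

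Ribosomal protein genes and p53 targets separated the knockdowns. Of 48 ribosomal protein genes 45 were lower in the PRMT5 than in the MEP50 knockdown, or 46 adjusted over the list alone, and the others did not pass (edgeR), by a median of -0.25 (camera adjusted p = 2.89e-16, and adjusted p = 0.162 with an estimated correlation), with RPL27 at -0.44 and RPL3 at -0.43. Under each of 3 other scalings 45 of them were lower as well, and the direction against the control stayed opposite in the knockdowns. The median difference of all genes was 0.0012 with TMM and -0.000191 to 0.0225 with the other scalings. Such small shifts could hardly have changed the outcome, so these counts are no test of the scaling. Of 34 p53 targets 22 were lower and 2 higher, or 23 and 2 adjusted over the list alone (camera adjusted p = 1.58e-06, and adjusted p = 0.102 with an estimated correlation), with CDKN1A at -0.80 and PLK2 at 0.53. Of 32 ATF4 and unfolded protein response genes 21 were lower and 3 higher, or 22 and 3 adjusted over the list alone (camera adjusted p = 0.000438, and adjusted p = 0.152 with an estimated correlation), with ASNS at -0.63 and VLDLR at -0.56. Of 27 NRF2 targets 18 were lower and 5 higher, or 19 and 5 adjusted over the list alone (camera adjusted p = 0.00148, and adjusted p = 0.288 with an estimated correlation), with GPX2 at -1.07 and AKR1C1 at -0.95. Of 7 fibroblast and stroma markers 6 were lower (camera adjusted p = 0.000995, and adjusted p = 0.102 with an estimated correlation), with COL1A1 at -0.85. Higher in the PRMT5 knockdown were 12 of 22 NF-kB and inflammatory genes, with 1 lower, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.00148, and adjusted p = 0.262 with an estimated correlation), and 13 of 25 sterol genes, with 3 lower, or 14 and 3 adjusted over the list alone (camera adjusted p = 0.00273, and adjusted p = 0.439 with an estimated correlation). So were 6 of 13 mitochondrially encoded genes, or 12 adjusted over the list alone (camera adjusted p = 0.000201, and adjusted p = 0.591 with an estimated correlation). The other 15 tested lists were not called between the knockdowns. Of these, the mesenchymal list (camera adjusted p = 0.0797) was called without a low-count filter (0.0134, mean log2 difference -0.38) and without MEP50 knockdown replicate 1 (0.0397, mean -0.41). The histone list (camera adjusted p = 0.0649, mean -0.11) was called without a low-count filter (0.0382, mean -0.02), without PRMT5 knockdown replicate 3 (0.00879, mean -0.17) and without MEP50 knockdown replicate 1 (0.0404, mean -0.10).

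**Figure D4:**
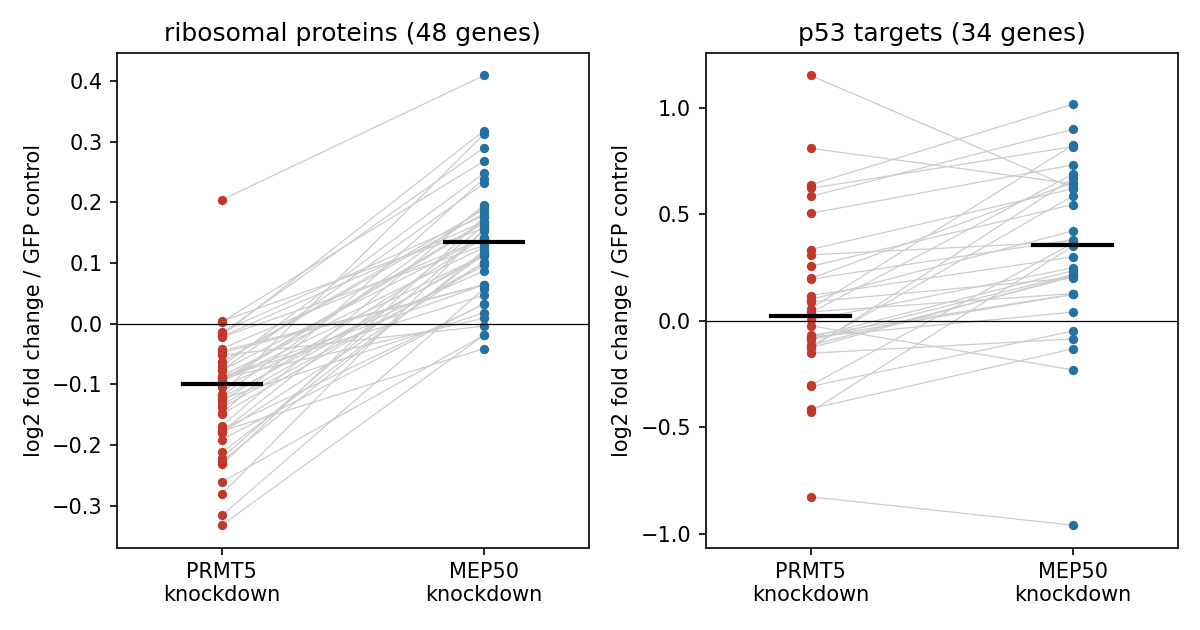
Log2 fold change against the GFP control of 48 ribosomal protein genes (left) and 34 p53 targets (right) in each knockdown; grey lines join the values of 1 gene and black bars are medians. The median of the ribosomal protein genes was -0.10 in the PRMT5 and 0.14 in the MEP50 knockdown, and that of the p53 targets 0.02 and 0.36.

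The authors' deposited tables of changed genes gave the same directions. The authors' deposited table for the PRMT5 knockdown held 6807 genes, 3415 higher and 3392 lower, and the authors' deposited table for the MEP50 knockdown held 6832, 3541 higher and 3291 lower. Of these genes 98.7% and 99.7% passed the edgeR test here with the same sign. Among the 6728 and 6821 of them that were tested here, 0 had the opposite sign. The authors' tables hold the same counts of the same libraries, so the shared directions are no independent evidence.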

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

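The tests of the shared-control noise, of a difference private to the control group, of the scaling and of the control hairpin for a part of the genes were chosen only after the result was seen. The others reported here were set out beforehand, but the plan for the trend test named transcript length and GC content and not mean expression.

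Ribosomal protein genes stood out because the change of most single members differed between the knockdowns in the direct edgeR test. The list was lower in the PRMT5 than in the MEP50 knockdown by a median log2 difference of -0.247, with RPL27 at -0.44 and RPL3 at -0.43. As a list it passed in camera with a preset correlation (adjusted p = 2.89e-16), and adjusted p = 0.162 with an estimated correlation. Removing the trend of the differences on transcript length, GC content and mean expression left a median of -0.209 (95% bootstrap interval over genes, taken as independent, -0.26 to -0.192), or 84.6% of its size, which argues against that trend as the whole cause. A scaling factor moves all genes of a library alike, so by itself it cannot part the list from the median of all genes. The list median lay -0.248 from that median (interval over genes, taken as independent, -0.273 to -0.214). With the median of all genes near 0, this value restates the difference that flagged the list and is no independent evidence against the scaling. Reads shared with processed pseudogenes were not tested and stay open, as does an effect of losing PRMT5 against losing MEP50, so a biological difference is only a hypothesis here.

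Other named genes were called against the control in opposite directions in the knockdowns and also differed between them in the same test. They were the proteoglycan gene LUM (-3.67), E-cadherin CDH1 (-1.12), the cell cycle inhibitor CDKN1A (-0.80) and WDR77 (1.81), the target of the MEP50 hairpin. The calls of CDH1, CDKN1A and WDR77 in the PRMT5 knockdown were lost under some alternatives, as given above. LUM fell in the PRMT5 knockdown (log2 fold change -3.06) and rose in the MEP50 knockdown (0.61). No explanation was tested for LUM, CDH1 or CDKN1A singly. Reads outside annotated genes, which no comparison used, made up 14.2% of all reads in the PRMT5 knockdown (13.7 to 14.5% in its 3 libraries) against 11.9 to 12.4% in the control libraries, and no explanation of this was tested. No group had the 4 libraries that the test for a single deviating library needs.

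Genes that differed between the knockdowns may in part be direct off-target effects of the MEP50 hairpin. Of 15929 words of 7 bases, GTCTTTG was the one whose carriers were lowest in the MEP50 knockdown (z = -6.72, against -5.93 for the most extreme of 100 permutations), and its z was -0.0118 in the PRMT5 knockdown. The shift was small: in the MEP50 knockdown its 1940 carriers had an unadjusted mean log2 fold change of -0.076, against 0.0108 for genes without it. The lowest word in the PRMT5 knockdown, TCCATAC, stayed within the permuted range (z = -4.31, against -5.06). GTCTTTG occurs in the WDR77 transcripts, as do 15.1% of all 7-base words, and DAZAP2 carries 2 sites, YWHAG 1 and CCL2 and PTX3 0. Carriers made up 26% of the genes lower in the MEP50 than in the PRMT5 knockdown and 13.8% of genes not called. For no word did the excess pass 13.8 percentage points (TGTCTTT), which argues against direct repression through any 1 word as the whole cause. Repression through several words or through sites outside 3' UTRs was not tested. These shares were not adjusted for UTR length or GC content. The hairpin sequence was not used here, so a seed effect on a part of these genes is a hypothesis that the sequence or a second hairpin would test.

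The changes shared by both knockdowns may in part belong to the control group. The covariance of the fold changes was 0.317 against at most 0.0247 in simulations of shared controls, which argues against counting noise. The 0.294 beyond the simulated mean cannot be told apart from a difference private to the 1 control group, since both knockdowns were set against it. The 3' UTR word with the highest values in both knockdowns was ACAACGT (z = 5.81, permuted at most 5.37), and whether the control hairpin lowered its carriers cannot be told apart from other causes because the target sequence was not used here. The largest excess of any word among genes higher in both was 16.8 percentage points (TTTTTTA, 56.8% against 40%), too small for seed repression of all of them through 1 word. Here too the shares were not adjusted for UTR length or GC content. A shared effect of losing either partner of the complex stays open.

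Of the 10 splits of the 6 libraries in each comparison, 1, the real one, gave as many edgeR calls: 7552, 7497 and 5606 for PRMT5, MEP50 and the direct comparison, with 0 in every other split. At an unadjusted p below 0.05 the highest other splits gave 172, 177 and 343 genes (DESeq2 was not run on the splits). With 10 splits a share under 0.05 cannot be reached.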

How the results depend on the processing

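No alternative here was chosen after the results were seen. Counts of genes and of shared genes stayed within 1.5 times their value under 3 other scalings, DESeq2, both other filters, fits of 6 libraries, and removal of small RNA and mitochondrial genes. The counts of genes per comparison also did so at an adjusted p below 0.01, which was not run for the shared counts. At 2-fold or more the edgeR counts were 513 and 544 (PRMT5 knockdown), 545 and 550 (MEP50 knockdown), and 224 and 241 between them, by construction of that threshold. The correlation of the fold changes was 0.591 without a low-count filter, 0.796 with a filter at 1 CPM and 0.791 in fits of 6 libraries; the cause was not tested.

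With an estimated correlation camera called 0, 0 and 0 lists; at an unadjusted p below 0.05 there were 3, 7 and 4, and the lowest adjusted p was 0.21, 0.0564 and 0.102. DESeq2 gives no camera value.

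Without the low-count filter the mean log2 fold change of the histone list reversed, to -0.05 (-0.0538) in the PRMT5 and -0.03 (-0.0349) in the MEP50 knockdown, while camera still called the list higher (adjusted p = 0.0333 and 0.000225) and its medians were 0.09 and 0.20; the cause was not tested. 3 measures of a list were tried for this comparison of settings: a signed camera adjusted p, the mean log2 fold change of members, and a difference of mean log2 CPM. The third was tried only after this reversal had been seen and was dropped, and the second was kept.

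Leaving out each library in turn gave 3354 to 3792 genes higher and 3323 to 3844 lower in the PRMT5 knockdown, 3453 to 3948 and 3342 to 3766 in the MEP50 knockdown, and 2256 to 2768 and 2569 to 3077 between them. Shared were 2261 to 2477 higher, 2059 to 2264 lower and 286 to 425 opposite, the correlation was 0.756 to 0.787, and 8 to 10, 13 to 14 and 8 to 10 lists were called.

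With the replicate number as a replicate block 3804 and 3619, 3874 and 3675, and 2775 and 2984 genes were called. The ATF4 list (adjusted p = 0.0503) and PRMT2 (edgeR adjusted p = 0.0562) in the MEP50 knockdown lost their call, and no other named gene or list did. Same-numbered libraries correlated by -0.0406 to 0.0412, and 1 library correlated best with its own number, so the numbers do not pair the libraries.

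Over all alternatives, values of named genes, called or not, kept their direction and their side of the threshold in 3335 cases and lost the call in 41, and 0 reversed. Values of lists, called or not, did so in 1190 cases, lost the call in 39, gained it in 8 and reversed in 2. At this depth and number of libraries, 76% of the genes with the smallest simulated change were recovered, against 98% at 2-fold. These genes had a control mean of at least 1 CPM and were simulated without the gene-by-gene part of the spread.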

Other observations

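The observations in this part were all chosen after the data were seen. Many collagen genes rose in both knockdowns, among them some already in the lists above, such as COL5A1, COL1A1 and COL3A1. Of 22 tested collagen genes 15 rose and 2 fell in the PRMT5 knockdown (median log2 fold change 0.58, camera adjusted p = 0.000376 over 381 gene families, and adjusted p = 0.952 with an estimated correlation), and 17 rose and 3 fell in the MEP50 knockdown (1.16, camera adjusted p = 0.000252, and adjusted p = 0.99 with an estimated correlation). COL13A1 was at 3.45 and 3.36, COL6A1 at 2.85 and 1.75 and COL18A1 at 2.19 and 1.82. The fibrinogen chains FGA (-3.78 and -3.29), FGB (-4.08 and -3.64) and FGG (-3.54 and -3.86) fell in both.

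Between the knockdowns zinc finger genes were higher in the PRMT5 knockdown (103 of 360, with 18 lower; camera adjusted p = 0.0047), as were 8 of 11 UTP genes of ribosomal RNA processing (camera adjusted p = 0.0207), and 11 of 15 aldehyde dehydrogenase genes were lower, with 1 higher (camera adjusted p = 0.0047). For each of these families it was adjusted p = 0.889 with an estimated correlation.

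The authors' deposited tables list the HTSeq line for reads outside genes as if it were a gene, with a log2 fold change of 0.26 in the PRMT5 and 0.16 in the MEP50 knockdown.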
